A study of Mus musculus with 24 samples.

How the data were processed

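The series holds 24 mouse samples on the C57BL6/J background, and its stated subject is how the transcription factors EBF1 and PAX5 regulate the Myc gene. RNA was sequenced from fetal liver pro-B cells that were wild type, lacked Ebf1 (Ebf1-KO) or lacked Pax5 (Pax5-KO) and were grown on OP9 stroma with KIT ligand, FLT3 ligand and IL-7. The cells carried the retroviral vector pMiG, either empty or encoding Ebf1 or Pax5. The 14 RNA libraries form 7 groups of 2: wild type with empty vector, Ebf1-KO with empty vector, Ebf1 or Pax5, and Pax5-KO with empty vector, Ebf1 or Pax5. EBF1 chromatin immunoprecipitation was done in the pre-B line 230-238, with 2 immunoprecipitated samples and an input, and gave 1 peak list. H3K4me3 PLAC-seq, which sequences chromatin contacts of fragments bearing the promoter mark H3K4me3, was done on 3 wild-type and 4 Ebf1-KO samples and was given as 1 pooled contact profile per genotype.

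RNA values were whole-number exon read counts per gene, which the authors made with HOMER, per the file headers, and which were deposited without normalization. Per the submitters' processing notes, the tools included STAR 2.6.0b-1, HOMER 4.8, DESeq2, Bowtie2 2.3.4.2 and 2.3.5, Trim Galore 0.6.4, FastQC, HiC-Pro 2.11.1, Picard and bedtools, on the mm10 genome; the notes give no roles or order. Strand was not given as a setting in the sources used here, so overlapping genes can share reads. Pax5 overlaps 5730488B01Rik and Mir5120, and its values carry that limit. The peak list was made by the authors with HOMER after comparing replicates by IDR, per the file headers and the labels. For each peak it gives a normalized tag count, which is a signal scaled by the authors, a findPeaks score set by the authors, and a fold change against the control, a ratio that the authors computed. Score and fold are the authors' values for that list and were used only to rank, filter or describe peaks within it. Each contact profile deposited holds a whole-number count of contacts per restriction fragment with the fragment at the start of the Myc transcript NM_001177354, a virtual 4C view. Fragments with 0 contacts are not listed in it, and the authors pooled the samples of a genotype, so contact shares have no replicate test.

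The count table holds 24506 genes. Its gene types include 20690 protein-coding genes and 3343 non-coding RNA genes. Every column of per-sample values was matched to a sample by its name, and 0 columns were left unused. The Pax5-KO empty-vector column without a number was taken as replicate 1, since the other column of that group is numbered 2. Exon counts ran from 16.1 to 42.1 M (mega) per library. A tag in the column names, called the run tag here, parts the libraries by replicate number. The headers and labels do not say what it marks. Replicate 1 libraries held 18.6 to 23.6 M exon counts, which is 32.4 to 44.4% of the totals in the file headers, and replicate 2 libraries held 16.1 to 42.1 M, or 28.5 to 65.4%. At the lowest of these depths a count of 0 in both libraries of a group was bounded with a floor of 3 counts over the group, and folds against such a group are given as "at least". Intervals and floors cover counting error only. Replicates of a group had Pearson correlations of log2 CPM from 0.895 to 0.971, and chi-square per degree of freedom of their counts from 73.7 to 323, so no pair looked like 1 library deposited under both numbers.

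Counts were tested in R 4.3.3 with edgeR 4.0.16: libraries were scaled by TMM, genes were kept by filterByExpr, and 1 quasi-likelihood fit over the 7 groups gave log2 fold changes, their standard errors and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. The fit tested 14550 genes. CPM values are counts per M of library size after TMM scaling, given as mean ± SD of 2 libraries, and log2 CPM used a prior count of 2. Every p-value of a gene in the results is an adjusted p of this test, and every list p-value an adjusted p of camera, unless another test is named. The labels do not say that replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical. In simulated data, mean levels were taken over all libraries and genes were changed in the group of Ebf1-KO with Ebf1. Over 14185 genes, 52 of 100 genes changed by 2 log2 units and 9 of 100 changed by 1 were called in the Ebf1-in-Ebf1-KO comparison. Of the called genes 0 had the wrong sign, and 0 unchanged genes were called by edgeR. In a simulated list test over 14550 genes, a raised list had an adjusted p of 9.6e-14 and 0 of 17 unchanged lists were called by camera. Those lists were random with independent genes, so this cannot show how often camera calls unchanged lists whose members move together.

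The 18 gene lists were fixed before the data were examined, as were their tests in the 6 main comparisons and the rule for named genes. They were ribosome biogenesis, nucleotide and one-carbon synthesis, glycolysis, DNA replication and G1/S, mitosis and G2/M, cell cycle brakes with the MXD family, the BCL2 family, the early B lineage, antigen receptor recombination, IL-7, PI3K and pre-B receptor signalling, the T lineage, NK and innate lymphoid cells, the myeloid lineage, stem and progenitor cells, erythroid cells and megakaryocytes, OP9-type stroma, the interferon response and sex-linked genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 18 lists of a comparison. The list tests of differing effects were chosen after the results were seen and adjusted over 36 tests, 18 lists for each of the 2 vectors. Member counts refer to genes past the threshold among all genes tested, and a second count was adjusted over the list alone. Of the 59 list calls in the 6 main comparisons, 26 held with an estimated correlation, 41 with fry and 59 with a replicate block. Median, mean and test had 1 sign for each list called. They differed in sign for some lists that did not pass, such as the BCL2 family in Ebf1-KO against wild type, whose median was -0.21 while its test pointed up. For some lists with members at 0 counts in 1 group, the median is also given with those members at their bound.

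Named genes were Myc, Ebf1 and Pax5 in every comparison, the 7 largest positive and 7 largest negative log2 fold changes among genes past the threshold with at least 10 CPM in the higher group and both of its libraries above both of the lower group, and the 3 smallest adjusted p-values of each list called. Predicted, Riken, pseudogene, miRNA and small RNA genes and single immunoglobulin or T cell receptor segments were passed over. For interactions, for the direct comparison of the vectors and for comparisons of add-back cells with wild type, the 4 largest changes each way were taken. List members named beyond this rule were chosen after their values were seen.

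The run tag and the labels' replicate numbers coincide, and a run below means the libraries that share both. Each run so defined held 1 library of each group, and values per library are also values within a run. Deviations from the group means were compared for pairs with the same number: pairs that include wild type correlated from -0.059 to 0.013, and the other 15 pairs from 0.076 to 0.236, with 13 of them above 0.1. The fit without the block was fixed as the reported one. The block was taken to mark a shared run because of the tag, which was seen before any fit. The pairs with wild type do not bear this out, so blocked values of comparisons with wild type rest on it as an assumption. A blocked value stands beside a result only where it changes a call or moves a count by more than 1.5 times.

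EBF1 peaks were assigned to the nearest transcription start in the count table within 100 kb, with start, end and strand as that table gives them, and called genes with and without a peak were compared with the tested genes not called, by Fisher's exact test (scipy 1.17.1, two-sided), adjusted over the 12 sets of genes. Contacts within 20 kb of the Myc start were left out. Shares of the remaining contacts were given with exact 95% binomial intervals, and ratios of shares with 95% intervals that cover counting error only. Contacts in bins of 10 kb with and without an EBF1 peak were compared by 1000 circular shifts of the peak positions. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate block, a fit of only the compared groups, leaving out each library, camera with an estimated correlation, camera with the block, fry, other distance and score limits for peaks, a logistic model with mean expression, and other windows and exclusions for contacts. Leaving out each library in the list tests was added after seeing the data. The EBF1 motif was not analysed here, and results of some genes are not reported here.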

Results

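RNA was counted in 14 libraries of mouse fetal liver pro-B cells, in 7 groups of 2, at 16.1 to 42.1 M exon counts per library (M, mega). For replicates 1 and 2 the totals in M were 21.1 and 16.1 in wild type, 20.5 and 27.1 in Ebf1-KO, 20.9 and 35.3 in Ebf1-KO with Ebf1, and 21.6 and 28.7 in Ebf1-KO with Pax5. They were 22.4 and 31.3 in Pax5-KO, 18.6 and 42.1 in Pax5-KO with Ebf1, and 23.6 and 36.1 in Pax5-KO with Pax5. EBF1 and PAX5 are transcription factors that B cell precursors need to enter and keep the B lineage, and MYC is a transcription factor that drives growth and division. Every level below is CPM as mean ± SD over the 2 libraries of a group, and every group without a named vector carried the empty one. On the first 4 principal components lay 27.4, 21.0, 10.9 and 9.16% of the variance of log2 CPM.

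The targeted genes were read first. Ebf1 (NM_007897, chromosome 11, 44618100 to 45008096, mm10) stood at 1034 ± 96.2 CPM in wild type, 263 ± 26.9 in Ebf1-KO and 278 ± 52.4 in Pax5-KO. Its libraries read 966 and 1102 in wild type, 244 and 282 in Ebf1-KO, 252 and 256 in Ebf1-KO with Pax5, 315 and 241 in Pax5-KO, and 488 and 589 in Pax5-KO with Pax5. With the Ebf1 vector they read 857 and 893 in Ebf1-KO and 1644 and 1483 in Pax5-KO. The counts cover all exons of the gene and the labels do not say which part was deleted, so the remaining reads in Ebf1-KO do not check that label. Pax5 (NM_008782, chromosome 4, 44531506 to 44710440, mm10) read 412 and 333 in wild type, 2.24 and 2.49 in Ebf1-KO, 37.2 and 33.1 in Ebf1-KO with Ebf1, and 429 and 399 in Ebf1-KO with Pax5. In Pax5-KO it read 20.1 and 12.3, with Ebf1 9.61 and 9.07, and with Pax5 746 and 439.6. Exon counts do not separate vector from endogenous transcripts.

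Myc (NM_010849, chromosome 15, 61985341 to 61990361, mm10) stood at 274 ± 36.1 CPM in wild type, 165 ± 30.5 in Ebf1-KO and 311 ± 47.8 in Pax5-KO. Adding Ebf1 to Ebf1-KO cells gave 363 ± 77.5 and adding Pax5 gave 75.6 ± 12.4, while in Pax5-KO cells Ebf1 gave 376 ± 97.8 and Pax5 gave 584 ± 121. By library, replicates 1 and 2 read 299 and 248 in wild type, 143 and 187 in Ebf1-KO, 308 and 418 with Ebf1, 66.8 and 84.3 with Pax5, 277 and 344 in Pax5-KO, 307 and 445 with Ebf1, and 499 and 670.2 with Pax5.

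**Figure D1:**
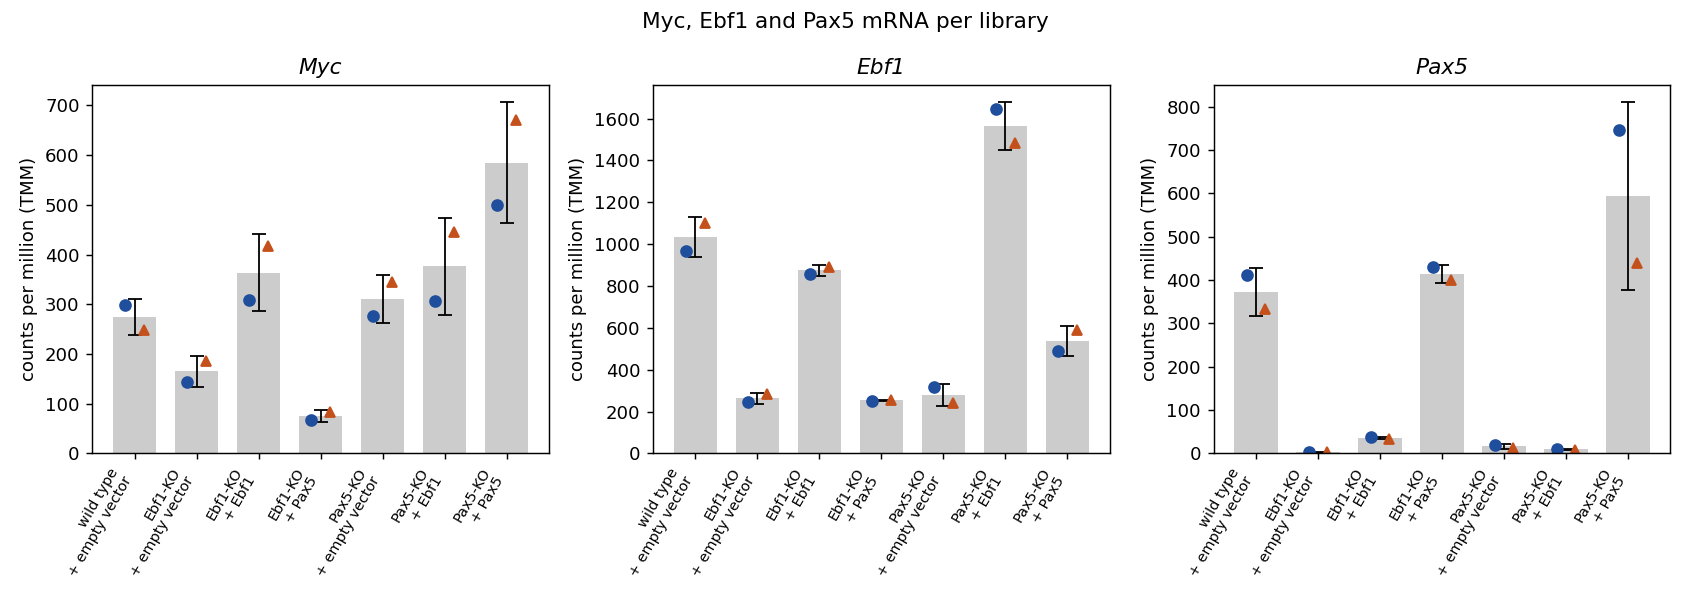
CPM after TMM scaling (y axis) of Myc, Ebf1 and Pax5 in the 7 RNA groups (x axis), with bars for the mean of 2 libraries, error bars for the SD, circles for replicate 1 and triangles for replicate 2. Myc lay lowest in Ebf1-KO with Pax5, at 75.6 ± 12.4, and highest in Pax5-KO with Pax5, at 584 ± 121.

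Loss of Ebf1 was compared with wild type to ask which genes depend on it. Genes of the early B lineage fell as a group: 24 of 25 members fell, and Bank1 did not pass (median log2 fold change -7.26, adjusted p = 2.1e-32). Pou2af1, a coactivator of B cell genes, had 2891 ± 125 CPM in wild type and 0.120 ± 0.0238 in Ebf1-KO (log2 fold change -14.52 ± 0.48 SE, adjusted p = 1.2e-10). Cd79a, a signalling chain of the B cell receptor, fell from 519 ± 130 to 0.534 ± 0.022 CPM (-9.92 ± 0.38, adjusted p = 3.4e-10). Vpreb3 was at least 5909-fold lower, Vpreb2, which codes for a surrogate light chain part, at least 1179.7-fold lower, and Cplx2 at least 9686-fold lower. Pax5 itself fell (-7.29 ± 0.35, adjusted p = 2.5e-09), and Myc did not pass (-0.73 ± 0.25, adjusted p = 0.068). With the replicate block Myc passed (-0.76, adjusted p = 0.00996). The blocked value assumes a shared run, but wild type deviations did not correlate by replicate number with those in other groups (-0.059 to 0.013).

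Of 10 tested genes for antigen receptor recombination, 4 fell in Ebf1-KO: Rag1, Rag2, Lig4 and Xrcc6 (list median -0.97, adjusted p = 0.00040). Rag1, a subunit of the recombinase, fell from 1019 ± 233 to 22.4 ± 1.17 CPM (-5.51 ± 0.25, adjusted p = 1.6e-09). Among the cell cycle brakes, 7 of 18 fell, Cdkn1a rose, and 10 did not pass (median -1.23, adjusted p = 0.0019); Btg1, an antiproliferative factor, fell by 3.18 on the log2 scale. In the mitosis list, Mki67, Aurkb, Cenpe, Cenpf and Kif11 fell and 15 of 20 did not pass (median -0.49, adjusted p = 0.00037, or adjusted p = 0.335 with an estimated correlation). Mki67, a proliferation marker, had 1330 ± 134 CPM against 4227 ± 291 (-1.67 ± 0.19, adjusted p = 2.1e-05). Cenpf did not pass without Ebf1-KO replicate 1 (adjusted p = 0.0768), nor did Kif11 (0.14), which also did not pass without wild type replicate 1 (0.0758). For IL-7, PI3K and pre-B receptor signalling, 7 of 21 fell, including the kinase Syk (-1.73 ± 0.23, adjusted p = 7.3e-05), Pik3r1 rose, and 13 did not pass (median -0.24, adjusted p = 0.0110, or adjusted p = 0.444 with an estimated correlation; adjusted p = 0.115 without Ebf1-KO replicate 1). For glycolysis, the regulator Pfkfb3 and the lactate carrier Slc16a1 fell and 15 of 17 did not pass (median -0.49, adjusted p = 0.0379, or adjusted p = 0.636 with an estimated correlation; without Ebf1-KO replicate 1 adjusted p = 0.396, without wild type replicate 1 0.248).

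Interferon response genes and 4 lists of other blood cells were higher in Ebf1-KO, while erythroid and megakaryocyte genes did not pass (adjusted p = 0.207). All 15 interferon response genes rose (median 5.87, or 5.67 with genes at 0 counts at their bound; adjusted p = 1.5e-18), among them Oasl2 (8.12 ± 0.55). Of 15 NK and innate lymphoid genes 11 rose and 4 did not pass (median 7.17, or 5.51 at the bound; adjusted p = 5.8e-11), with Il2rb, a cytokine receptor chain, at 9.21 ± 0.43 and Cd7 at a ratio of 1285 (counting interval 399 to 11908). Of 19 myeloid genes 14 rose and 5 did not pass (median 6.34, or 5.93 at the bound; adjusted p = 1.4e-10), including lysozyme Lyz2 (7.01 ± 0.54) and the adaptor Tyrobp (8.14 ± 0.69). Summed over the list, myeloid genes had 47.2 and 40.7 CPM in the wild-type libraries and 792 and 783 in Ebf1-KO. In the T lineage list 11 of 18 rose, such as the kinase Lck (3.84 ± 0.27) and Cd28 (6.62 ± 0.34), Hes1 and Il2ra fell, and 5 did not pass (median 3.62, adjusted p = 0.00037). Of 14 stem and progenitor genes 6 rose, Erg and Cd93 fell and 6 did not pass (median 2.08, adjusted p = 0.0150, or adjusted p = 0.192 with an estimated correlation). The cytokine receptor Flt3 rose from 2.91 ± 0.743 to 378 ± 30.3 CPM (7.02 ± 0.26, adjusted p = 3.2e-10), and Cd34, which overlaps Gm16897, was at least 3381-fold higher. Other large rises were Tnni1, at least 1969-fold, and Fyb, at least 1088-fold.

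In Ebf1-KO against wild type 1167 genes rose and 967 fell, with 3888 at an unadjusted p under 0.05. Without wild type replicate 2, Ebf1-KO replicate 1 or Ebf1-KO replicate 2 the numbers were 683, 816 and 752 higher and 613, 511 and 599 lower. Adjusted over the list alone, 24 early B genes fell and 1 rose, 9 brakes fell and 2 rose, and 9 mitosis genes and 5 recombination genes fell. On the same basis 16 myeloid, 15 interferon and 12 NK and innate lymphoid genes rose and 0 fell, 11 T lineage genes rose and 4 fell, and 8 stem and progenitor genes rose and 4 fell. Lists that did not pass were ribosome biogenesis (median 0.18, adjusted p = 0.600), nucleotide and one-carbon synthesis (-0.14, 0.384), DNA replication (-0.19, 0.198), erythroid genes (2.83, 0.207), the BCL2 family (-0.21, 0.867), OP9-type stroma (0.23, 0.867) and sex-linked genes (0.21, 0.927).

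Loss of Pax5 was set against the same wild-type libraries. Of 25 early B genes 21 fell, Bank1 rose, and Vpreb2, Igll1 and Blk did not pass (median -3.04, adjusted p = 8.0e-21). Pou2af1 fell from 2891 ± 125 to 107 ± 34.1 CPM (-4.75 ± 0.30, adjusted p = 6.9e-08). Enpep, a membrane aminopeptidase of B cell precursors, was at least 4808-fold lower, and Alpl, a phosphatase, at least 2819.6-fold lower. Rag1, Rag2, Lig4 and Dclre1c fell among 10 recombination genes (median -1.17, adjusted p = 0.0039). Ebf1 fell (-1.89 ± 0.20, adjusted p = 8.7e-06), Pax5 fell (-4.53 ± 0.30, adjusted p = 1.5e-07), and Myc did not pass (0.18 ± 0.25, adjusted p = 0.69).

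All 15 interferon genes rose in Pax5-KO (median 5.33, or 5.03 at the bound; adjusted p = 3.9e-18). In the NK and innate lymphoid list 12 of 15 rose (median 6.05, or 5.55 at the bound; adjusted p = 7.7e-12), Il2rb from 0.138 ± 0.0481 to 197 ± 22.8 CPM. In the myeloid list 13 of 19 rose (median 6.52, or 5.31 at the bound; adjusted p = 7.4e-11), Lyz2 to 160.4 ± 2.50 CPM, and the list summed to 578 and 751 CPM in the Pax5-KO libraries. In the T lineage list 9 of 18 rose, Dtx1 fell and 8 did not pass (median 2.16, or 2.38 at the bound; adjusted p = 2.4e-05); Tcf7, a transcription factor of early T cells, rose from 1.19 ± 1.03 to 206 ± 31.5 CPM (7.41 ± 0.50, adjusted p = 1.6e-07). Of 14 stem and progenitor genes 6 rose, led by Flt3 (6.36 ± 0.26, adjusted p = 1.5e-09), Erg and Bcl11a fell, and 6 did not pass (median 2.01, adjusted p = 0.0024, or adjusted p = 0.0874 with an estimated correlation). Of 18 cell cycle brakes 6 fell, such as Btg1 (-2.76 ± 0.33), and Cdkn1a and Mxd1 rose (median -0.98, adjusted p = 0.00042). Mki67, Aurkb, Cenpe, Cenpf and Kif11 fell and 15 of 20 mitosis genes did not pass (median -0.31, adjusted p = 0.0018, or adjusted p = 0.405 with an estimated correlation), and Kif11 lost its call without any 1 of the 4 libraries (largest adjusted p = 0.095). Sex-linked genes moved together with the genotype: Xist, transcribed from an inactive X, rose to 3664 ± 1394 CPM from 15.0 ± 20.6, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty fell (median -10.70, or -9.98 at the bound; adjusted p = 4.5e-07). Of the calls of this comparison 44 lay on X and 4 on Y, 2.22% on X against 3.18% of the genes tested.

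Glycolysis passed downward in Pax5-KO with Pfkp and Pgk1 lower and Hk1 higher among 17 (median -0.56, adjusted p = 0.0111, or adjusted p = 0.517 with an estimated correlation). It did not pass without wild type replicate 1 (0.119) or Pax5-KO replicate 1 (0.0928). Ribosome biogenesis passed upward with Bop1, Gnl3 and Mybbp1a higher and 23 of 26 not passing (median 0.41, adjusted p = 0.0185, or adjusted p = 0.565 with an estimated correlation), and did not pass without wild type replicate 1 (0.0693) or Pax5-KO replicate 2 (0.0976). Of these 6 genes each lost its call without 3 or 4 of the 4 libraries in turn, with largest adjusted p of 0.172 for Pfkp, 0.19 for Pgk1, 0.201 for Hk1, 0.259 for Bop1, 0.125 for Gnl3 and 0.389 for Mybbp1a. In all, 1259 genes rose and 727 fell, with 3879 at an unadjusted p under 0.05. Without wild type replicate 1, wild type replicate 2 and Pax5-KO replicate 2 there were 895, 672 and 722 higher and 474, 351 and 290.0 lower. Adjusted over the list alone, 22 early B genes fell and 1 rose, 10 brakes fell and 2 rose, and 8 mitosis genes fell. Likewise 16 myeloid, 15 interferon and 13 NK and innate lymphoid genes rose and 0 fell, 10 T lineage genes rose and 3 fell, and 8 stem and progenitor genes rose and 3 fell. The IL-7 and PI3K list did not pass (median 0.30, adjusted p = 0.685), nor did nucleotide synthesis (0.22, 0.649), DNA replication (0.12, 0.931), the BCL2 family (0.57, 0.382), erythroid genes (adjusted p = 0.649) or stroma (adjusted p = 0.628).

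Both knockouts were compared with the same 2 wild-type libraries. They shared 795 higher genes, against 101 if the lists were independent, and 507 lower genes, against 48.3. Simulated unchanged groups shared at most 0 called genes by edgeR. Such groups hold no changed genes to call, so that number does not show how far shared controls raise the overlap. The correlation of fold changes across genes was 0.774, against 0.516 in simulation, and the covariance was 4.43 against 0.482, a difference of 3.95. The wild-type group has only 2 libraries and was not split, so part of the excess may come from the shared controls.

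**Figure D2:**
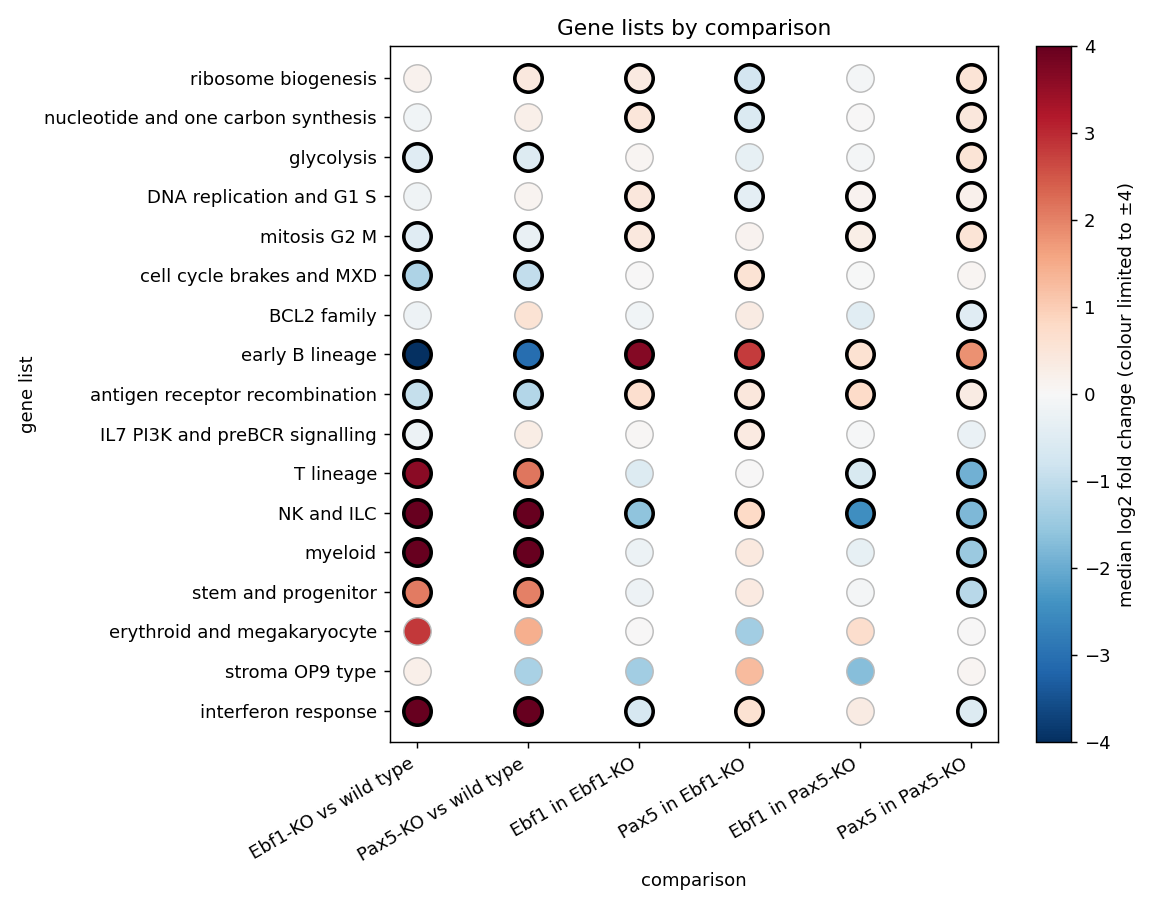
Median log2 fold change of 17 gene lists (y axis) in 6 comparisons (x axis), as dots coloured by the median on a scale limited to ±4, with a thick outline where camera gave an adjusted p under 0.05. The early B lineage was lower in both knockouts (medians -7.26 and -3.04) and higher after Ebf1 or Pax5 was added to Ebf1-KO cells (3.66 and 2.79) and Pax5 to Pax5-KO cells (1.82).

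Ebf1 added to Ebf1-KO cells raised early B genes: 17 of 25 rose and 8 did not pass (median 3.66, adjusted p = 1.2e-31; 18 rose and 1 fell adjusted over the list alone). Cd24a, a surface marker of B cell precursors, rose from 56.5 ± 2.20 to 1778 ± 213 CPM (4.98 ± 0.23, adjusted p = 7.4e-09), and Cd79b from 3.52 ± 0.583 to 126 ± 4.31 (5.15 ± 0.26, adjusted p = 1.5e-08). Vpreb2 was at least 911-fold higher, Col26a1, a collagen, at least 1218-fold and Apoa4, an apolipoprotein, at least 652-fold. Rag1 rose from 22.4 ± 1.17 to 525 ± 6.52 CPM (4.55 ± 0.24, adjusted p = 2.1e-08), and Rag1 and Rag2 were the 2 of 10 recombination genes that rose (median 0.68, adjusted p = 0.00014). Pax5 rose (3.89 ± 0.31, adjusted p = 2.3e-06). Myc rose from 165 ± 30.5 to 363 ± 77.5 CPM (1.14 ± 0.25, adjusted p = 0.021), in both runs, and did not pass without Ebf1-KO replicate 1 (0.93, adjusted p = 0.307), Ebf1-KO replicate 2 (1.36, adjusted p = 0.0514) or Ebf1-KO with Ebf1 replicate 2 (0.90, adjusted p = 0.302).

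The growth and division lists named here passed upward with Ebf1 at the preset correlation. None of them passed with an estimated correlation or with fry (fry adjusted p = 0.0766 to 0.242). Ccnd3, a D-type cyclin that overlaps Bysl, Uhrf1, Ccnd2 and Rrm2 rose among 26 DNA replication genes (median 0.44, adjusted p = 5.9e-06, or adjusted p = 0.342 with an estimated correlation), Ccnd3 by 1.53 ± 0.24 and Uhrf1 by 1.80 ± 0.26. Ccnd2 did not pass without Ebf1-KO replicate 1 (adjusted p = 0.0724). In the mitosis list Mki67 rose (median 0.41, adjusted p = 8.4e-05, or adjusted p = 0.342 with an estimated correlation), a call lost without any 1 of the 4 libraries: 0.243 and 0.0574 without Ebf1-KO replicates 1 and 2, 0.0673 and 0.166 without Ebf1-KO with Ebf1 replicates 1 and 2. Impdh1, an enzyme of guanine nucleotide synthesis, rose from 17.9 ± 5.57 to 169 ± 6.53 CPM (3.24 ± 0.29, adjusted p = 8.8e-06) and was the 1 of 22 nucleotide genes that passed (median 0.47, adjusted p = 0.00022, or adjusted p = 0.427 with an estimated correlation). Ribosome biogenesis passed upward (median 0.37, adjusted p = 0.0023, or adjusted p = 0.469 with an estimated correlation) with 0 of 26 members called by edgeR, 5 at an unadjusted p under 0.05 and 0 by DESeq2. It did not pass without Ebf1-KO replicate 1 (0.0966) or Ebf1-KO with Ebf1 replicate 2 (0.0663).

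NK and innate lymphoid genes fell with Ebf1: Il2rb (-2.45 ± 0.27, adjusted p = 6.9e-05), Cd7 (-3.50 ± 0.41, adjusted p = 0.00012) and Klrd1 fell, Gzma rose and 11 of 15 did not pass (median -1.59, adjusted p = 5.9e-06; 7 fell and 1 rose adjusted over the list alone). Klrd1 lost its call without any 1 library (largest adjusted p = 0.454) and Gzma without Ebf1-KO replicate 2 (0.192) or Ebf1-KO with Ebf1 replicate 1 (0.0594). Interferon genes were lower as a list (median -0.67, adjusted p = 0.00010, or adjusted p = 0.117 with an estimated correlation), with Oasl2 lower at 35.7 ± 12.7 against 280.0 ± 33.5 CPM (-2.97 ± 0.41, adjusted p = 0.00053) and 14 of 15 not passing. Other lists did not pass: glycolysis (median 0.08, adjusted p = 0.450), brakes (0.01, 0.652), the BCL2 family (-0.15, 0.065), IL-7 and PI3K (0.04, 0.065), T lineage (-0.53, 0.809), myeloid (-0.25, 0.332), stem and progenitor (-0.19, 0.620), erythroid (adjusted p = 0.986), stroma (-1.38, 0.0623) and sex-linked genes (adjusted p = 0.730). In all 321 genes rose and 111 fell, with 1615 at an unadjusted p under 0.05. Without Ebf1-KO replicates 1 and 2 there were 153 and 185 higher and 51 and 34 lower, and without Ebf1-KO with Ebf1 replicates 1 and 2 there were 231 and 191 higher and 27 and 24 lower.

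Pax5 added to Ebf1-KO cells raised 18 of 25 early B genes (median 2.79, or 2.69 at the bound; adjusted p = 1.4e-25; 22 rose adjusted over the list alone). Foxo1, a transcription factor that acts early in B cell development, rose from 22.1 ± 1.23 to 133 ± 7.86 CPM (2.58 ± 0.18, adjusted p = 2e-06), and Rag1 from 22.4 ± 1.17 to 153 ± 16.8 (2.77 ± 0.22, adjusted p = 4.9e-06). Rag1 and Rag2 were the 2 recombination genes that rose (median 0.45, adjusted p = 0.0019, or adjusted p = 0.0541 with an estimated correlation), and Dntt passed with the replicate block (3.09, adjusted p = 0.049). Ebf1 did not pass (-0.05 ± 0.19, adjusted p = 0.95). Myc fell from 165 ± 30.5 to 75.6 ± 12.4 CPM (-1.13 ± 0.25, adjusted p = 0.021), in both runs, and did not pass without Ebf1-KO replicate 2 (-0.90, adjusted p = 0.182), Ebf1-KO with Pax5 replicate 1 (-0.94, adjusted p = 0.161) or Ebf1-KO with Pax5 replicate 2 (-1.34, adjusted p = 0.0502).

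Cell cycle brakes rose with Pax5 in Ebf1-KO cells: Btg1 went from 23.2 ± 5.56 to 210.2 ± 32.4 CPM (3.18 ± 0.33, adjusted p = 7.7e-05), Btg2, Cdkn2d and Tob1 rose, and 14 of 18 did not pass (median 0.58, or 0.61 at the bound; adjusted p = 7.7e-06; 7 rose adjusted over the list alone). Ribosome biogenesis fell, with Gnl3, a nucleolar GTPase (-1.42 ± 0.21, adjusted p = 0.0012), Nop56, Nop58, Wdr43 and Ppan lower among 26 (median -0.75, adjusted p = 1.0e-06, or adjusted p = 0.319 with an estimated correlation). Btg2 did not pass without Ebf1-KO replicate 1 (0.0848) or Ebf1-KO with Pax5 replicate 1 (0.0558). Cdkn2d did not pass without any 1 library (largest 0.132), and Nop58 and Wdr43 not without 3 of the 4 (largest 0.115 and 0.19, both without Ebf1-KO with Pax5 replicate 1). Nucleotide synthesis passed downward (median -0.58, adjusted p = 0.00011, or adjusted p = 0.366 with an estimated correlation) with 0 of 22 called by edgeR, 8 lower at an unadjusted p under 0.05 and 2 lower by DESeq2. With the replicate block Phgdh (-1.13, adjusted p = 0.025) and Shmt2 (-0.71, 0.0284) passed. DNA replication passed downward too (median -0.40, adjusted p = 0.0033, or adjusted p = 0.392 with an estimated correlation) with 0 of 26 called by edgeR, 9 lower and 1 higher at an unadjusted p under 0.05 and 1 lower by DESeq2. With the replicate block Gins2 (-0.86, adjusted p = 0.0479) and Ccnd3 (0.66, 0.0246) passed. Without Ebf1-KO replicate 2 or Ebf1-KO with Pax5 replicate 1 the adjusted p of the list was 0.0994 and 0.249. In the IL-7 and PI3K list Syk (1.58 ± 0.23), Lyn, Btk, Inpp5d and Plcg2 rose, and the IL-7 receptor gene Il7r, from 216 ± 8.00 to 94.4 ± 6.44 CPM (-1.19 ± 0.20, adjusted p = 0.0031), and Socs2 fell (median 0.37, adjusted p = 0.0019, or adjusted p = 0.369 with an estimated correlation). Lyn did not pass without Ebf1-KO replicate 1 (0.0608).

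NK and innate lymphoid genes passed upward (median 0.79, adjusted p = 0.0142, or adjusted p = 0.131 with an estimated correlation) with 0 of 15 called by edgeR, 4 higher at an unadjusted p under 0.05 and 1 by DESeq2, and not without Ebf1-KO with Pax5 replicate 1 (0.121). Interferon genes passed upward with 1 of 15 called (median 0.62, adjusted p = 0.0172, or adjusted p = 0.319 with an estimated correlation), and not without Ebf1-KO replicate 2 (0.0577) or Ebf1-KO with Pax5 replicate 2 (0.322). With the replicate block Il2rb (0.97, adjusted p = 0.0111) and the interferon gene Zbp1 (1.98, 0.0422) passed. Klhl14, a B cell gene of the Kelch family that overlaps 4930426D05Rik, was at least 795-fold higher, and Slamf6, a lymphocyte receptor, at least 737-fold. In all 458 genes rose and 136 fell, 264 with the replicate block, and 2430.0 had an unadjusted p under 0.05. Without Ebf1-KO replicates 1 and 2 there were 131 and 224 higher and 28 and 38 lower, and without Ebf1-KO with Pax5 replicates 1 and 2 there were 291 and 231 higher and 66 and 59 lower. Lists that did not pass were glycolysis (median -0.31, adjusted p = 0.117), mitosis (0.13, 0.379), the BCL2 family (0.33, 0.117), T lineage (0.03, 0.257), myeloid (0.38, 0.269), stem and progenitor (0.37, 0.117), erythroid (adjusted p = 0.882), stroma (1.28, 0.174) and sex-linked genes (adjusted p = 0.519).

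Ebf1 added to Pax5-KO cells raised 7 early B genes, lowered Cd79a, Cd72 and Cd38, and left 15 of 25 not passing (median 0.60, adjusted p = 0.0032; 10 rose and 3 fell adjusted over the list alone). Foxo1 rose from 197 ± 10.4 to 484 ± 19.4 CPM (1.30 ± 0.17, adjusted p = 0.00096), Lef1 by 2.09 ± 0.30 and Cplx2 by 2.73 ± 0.28. Apoa4 was at least 956-fold higher. NK and innate lymphoid genes fell: Il2rb (-2.02 ± 0.27, adjusted p = 0.001), Cd7 (-2.54 ± 0.39, adjusted p = 0.0024), Nkg7, Id2 and Klrb1c fell, Gzma rose and 9 of 15 did not pass (median -2.49, or -2.22 at the bound; adjusted p = 0.00024). Myc did not pass (0.28 ± 0.25, adjusted p = 0.57), and without Pax5-KO with Ebf1 replicate 2 its log2 fold change was -0.024. Ebf1 rose to 1563 ± 114 CPM (2.49 ± 0.20, adjusted p = 2.9e-05) and Pax5 did not pass (-0.79 ± 0.27, adjusted p = 0.13).

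The other lists called with Ebf1 in Pax5-KO cells each lost their call when 1 library was left out. In the T lineage Cd28 and Cd2 fell and Cd247 rose (median -0.64, or -0.87 at the bound; adjusted p = 0.0289, or adjusted p = 0.174 with an estimated correlation). Mitosis had Mki67 higher (median 0.27, adjusted p = 0.0289, or adjusted p = 0.699 with an estimated correlation). DNA replication had Mcm10 and Ccnd3 higher (0.14, adjusted p = 0.0421, or adjusted p = 0.699 with an estimated correlation), and recombination Rag1 and Rag2 (0.77, adjusted p = 0.0421, or adjusted p = 0.174 with an estimated correlation). Without Pax5-KO with Ebf1 replicate 2 the adjusted p was 0.0982 for the early B list, 0.0982 for the T lineage, 0.491 for mitosis, 0.66 for DNA replication and 0.395 for recombination, so 1 list passed in place of 6. Without Pax5-KO replicate 1 it was 0.215 for mitosis, 0.343 for DNA replication and 0.0671 for recombination. Without Pax5-KO replicate 2 it was 0.0902 for the T lineage and 0.0818 for recombination. Of the genes named, Cd247, Cd28, Mki67, Mcm10, Ccnd3 and Rag2 lost their calls without 2 or 3 libraries, and Rag1 without Pax5-KO replicate 2, with largest adjusted p of 0.235, 0.164, 0.261, 0.117, 0.151, 0.11 and 0.121. With the replicate block Cdk6 of the DNA replication list passed (0.72, adjusted p = 0.0419). The replicates of Pax5-KO with Ebf1 had the lowest correlation of any group, 0.895. In all 255 genes rose and 269 fell (439 with the replicate block), with 3005 at an unadjusted p under 0.05. Without Pax5-KO replicates 1 and 2 there were 131 and 53 higher and 186 and 72 lower, and without Pax5-KO with Ebf1 replicate 2 there were 830.0 higher and 1398 lower.

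Of the lists that did not pass with Ebf1 in Pax5-KO cells, ribosome biogenesis had a median of -0.07 (adjusted p = 0.965), myeloid -0.32 (0.223), interferon 0.32 (0.223) and the BCL2 family -0.45 (0.0855). The adjusted p was 0.965 for nucleotide synthesis, 0.941 for glycolysis, 0.608 for brakes, 0.983 for IL-7 and PI3K, 0.965 for stem and progenitor, 0.674 for erythroid, 0.223 for stroma and 0.983 for sex-linked genes.

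Pax5 added to Pax5-KO cells raised 19 of 25 early B genes, with Vpreb2, Igll1, Blk, Cd72, Bank1 and Spib not passing (median 1.82, adjusted p = 1.1e-22; 20 rose adjusted over the list alone). Cd79a rose from 65.7 ± 18.8 to 556 ± 52.0 CPM (3.08 ± 0.26, adjusted p = 8.4e-06) and the adaptor Blnk from 0.868 ± 0.758 to 186 ± 30.0 (7.63 ± 0.65, adjusted p = 8.4e-06). Enpep, Klhl14 and Alpl were at least 1206-fold, at least 1044-fold and at least 739-fold higher. Rag1 (from 187 ± 35.6 to 529.6 ± 26.8 CPM, adjusted p = 0.00073) and Rag2 (2.08 ± 0.22, adjusted p = 4.8e-05) rose among 10 recombination genes (median 0.33, adjusted p = 0.0187, or adjusted p = 0.108 with an estimated correlation). Myc had 311 ± 47.8 CPM before and 584 ± 121 after (0.91 ± 0.25, adjusted p = 0.060, not passing; with the replicate block 0.91, adjusted p = 0.00893). Ebf1 rose (0.95 ± 0.19, adjusted p = 0.009), and did not pass without Pax5-KO replicate 2 (0.192) or Pax5-KO with Pax5 replicate 2 (0.16).

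T lineage genes fell with Pax5: Notch1, a receptor that directs T cell fate, from 793 ± 25.5 to 187 ± 17.2 CPM (-2.08 ± 0.20, adjusted p = 2e-05), Cd28 (-2.27 ± 0.27), Lck (-1.78 ± 0.24), Tcf7, Il2ra and Ptcra fell and 12 of 18 did not pass (median -1.93, or -2.08 at the bound; adjusted p = 2.8e-08; 9 fell and 1 rose adjusted over the list alone). In the NK and innate lymphoid list Il2rb (-2.04 ± 0.27, adjusted p = 0.00034), Cd7 and Id2 fell (median -1.79, adjusted p = 3.2e-06). In the myeloid list Fcer1g (-4.33 ± 0.58, adjusted p = 0.00045), Lyz2, Tyrobp and Ly6c2 fell and 15 of 19 did not pass (median -1.47, adjusted p = 3.2e-06). The list summed to 181 and 182 CPM. Flt3 fell from 239 ± 1.75 to 21.5 ± 1.38 CPM (-3.48 ± 0.22, adjusted p = 7e-07). Cd34 and Cd93 also fell and Kit (1.84 ± 0.26, adjusted p = 0.00071), Erg and Bcl11a rose in the stem and progenitor list (median -1.09, adjusted p = 0.0303, or adjusted p = 0.274 with an estimated correlation), which did not pass without any 1 of the 4 libraries (largest 0.156). Ptcra, Id2 and Lyz2 lost their calls without any 1 library (largest adjusted p = 0.325, 0.373 and 0.293). Tyrobp lost its call without Pax5-KO replicate 2 (0.0741) or Pax5-KO with Pax5 replicate 2 (0.157), and Cd7 without the latter (0.0905).

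Mitosis passed upward with Pax5 in Pax5-KO cells, with Mki67 higher (median 0.56, adjusted p = 1.9e-05, or adjusted p = 0.274 with an estimated correlation). Ribosome biogenesis passed upward (median 0.53, adjusted p = 6.7e-05, or adjusted p = 0.323 with an estimated correlation) with 0 of 26 called by edgeR, 9 higher at an unadjusted p under 0.05 and 2 by DESeq2. Glycolysis had the lactate dehydrogenase Ldha higher (0.54, adjusted p = 0.0027, or adjusted p = 0.425 with an estimated correlation; 4 rose adjusted over the list alone). DNA replication had Ccnd3 (1.66 ± 0.24, adjusted p = 0.00079), Rrm2 and Tyms higher and Ccnd2 lower (0.20, adjusted p = 0.0091, or adjusted p = 0.501 with an estimated correlation). Nucleotide synthesis passed upward (0.44, adjusted p = 0.0303, or adjusted p = 0.537 with an estimated correlation) with 0 of 22 called by edgeR, 4 higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. Interferon genes passed downward (-0.55, adjusted p = 0.0303, or adjusted p = 0.323 with an estimated correlation) with 0 of 15 called by edgeR, 2 lower at an unadjusted p under 0.05 and 0 by DESeq2. In the BCL2 family the survival factor Bcl2 (-1.19 ± 0.20, adjusted p = 0.0025), Pmaip1 and Bmf fell and Bcl2l1 rose (-0.49, adjusted p = 0.0402, or adjusted p = 0.220 with an estimated correlation). With the replicate block Utp20 (0.61, adjusted p = 0.0483) and Wdr43 (0.74, 0.0286) of ribosome biogenesis, Slc16a1 (0.97, 0.0386) and Eno1 (1.18, 0.0427) of glycolysis, Ctps (1.06, 0.0413) of nucleotide synthesis, Cenpe (0.77, 0.0315) of mitosis and Dclre1c (0.95, 0.041) of recombination also passed.

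Several of these calls rested on single libraries. Without Pax5-KO replicate 1 the adjusted p was 0.0655 for glycolysis, 0.131 for DNA replication, 0.212 for nucleotide synthesis and 0.0682 for interferon genes. Without Pax5-KO with Pax5 replicate 2 it was 0.113, 0.157, 0.646 and 0.145. Without Pax5-KO replicate 2 it was 0.0808 for interferon genes and 0.279 for the BCL2 family, which also did not pass without Pax5-KO with Pax5 replicate 1 (0.0692) or replicate 2 (0.0784). Of the genes, Bmf and Ccnd2 lost their calls without any 1 library (largest adjusted p = 0.361 and 0.158), and Bcl2l1 and Ldha without 3 (0.208 and 0.534). Mki67 lost its call without Pax5-KO replicate 2 (0.245) or Pax5-KO with Pax5 replicate 1 (0.164), and Rrm2 without Pax5-KO with Pax5 replicate 2 (0.0731). In all 238 genes rose and 349 fell, with 2140.0 at an unadjusted p under 0.05. Without Pax5-KO replicates 1 and 2 there were 144 and 95 higher and 251 and 168 lower, and without Pax5-KO with Pax5 replicates 1 and 2 there were 138 and 105 higher and 136 and 117 lower. Of the 18 lists 13 passed, and 8 without Pax5-KO replicate 1 or without Pax5-KO with Pax5 replicate 2. Brakes (median 0.08, adjusted p = 0.997), IL-7 and PI3K (-0.26, 0.165), erythroid (adjusted p = 0.389), stroma (adjusted p = 0.419) and sex-linked genes (adjusted p = 0.781) did not pass.

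In Ebf1-KO cells Myc was higher with Ebf1 than with Pax5 (2.26 ± 0.26, adjusted p = 5.7e-05). Tnnt2, a troponin, was at least 3063-fold and Col26a1 at least 1297-fold higher with Ebf1, and Klhl14 was lower at a ratio of 2056 (counting interval 469.8 to 103510.0). In Pax5-KO cells Myc did not pass (-0.64 ± 0.25, adjusted p = 0.145; with the replicate block -0.64, adjusted p = 0.0434), and it passed without Pax5-KO with Ebf1 replicate 2 (-0.94, adjusted p = 0.0381). There Klhl14 was at least 1066-fold and Alpl at least 754-fold lower with Ebf1 than with Pax5. The vectors differed in 1484 genes in Ebf1-KO cells and in 992 in Pax5-KO cells. Without Ebf1-KO with Ebf1 replicates 1 and 2 or Ebf1-KO with Pax5 replicates 1 and 2 the former was 674, 635, 939 and 918. Without Pax5-KO with Ebf1 replicate 2 or Pax5-KO with Pax5 replicates 1 and 2 the latter was 2644, 419 and 333.

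The effect of each vector was compared between the knockouts by an interaction term in the same fit. For Myc the Pax5 effect was higher in Pax5-KO than in Ebf1-KO cells by 2.04 ± 0.36 log2 units (adjusted p = 0.0062), by 1.95 and 2.11 within the 2 runs. It passed with any 1 library left out (1.77 to 2.24, largest adjusted p = 0.047). The Ebf1 effect on Myc did not differ past the threshold (-0.86 ± 0.35, adjusted p = 0.52). The Pax5 effect differed for 460.0 genes, 107 higher and 353 lower in Pax5-KO, and the Ebf1 effect for 89, 5 higher and 84 lower, with 2374 and 1219 at an unadjusted p under 0.05. With the replicate block the former was 737, and included Ebf1 (1.00, adjusted p = 0.0273), which did not pass without it (1.00, 0.0591). Without Ebf1-KO replicates 1 and 2, Ebf1-KO with Pax5 replicate 2, Pax5-KO replicate 2 and Pax5-KO with Pax5 replicates 1 and 2 it was 133, 243, 254, 193, 226 and 144. Without Ebf1-KO replicate 1, Ebf1-KO with Ebf1 replicate 2, Pax5-KO replicate 2 and Pax5-KO with Ebf1 replicate 2 the latter was 48, 56, 53 and 685.

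Add-back cells were also set against wild type. Ebf1-KO cells with Ebf1 differed in 1624 genes, among them Enpep, at least 4853-fold lower, and Pax5 (-3.41 ± 0.29, adjusted p = 1.6e-06), while Myc (0.41 ± 0.25, adjusted p = 0.37) and Ebf1 (-0.24 ± 0.19, adjusted p = 0.51) did not pass. Without wild type replicate 2, Ebf1-KO with Ebf1 replicate 1 or replicate 2 the number was 893, 934 and 879. Pax5-KO cells with Pax5 differed in 1038 genes. Myc was higher than in wild type (1.09 ± 0.25, adjusted p = 0.016), and did not pass without wild type replicate 2 (0.94, adjusted p = 0.207) or Pax5-KO with Pax5 replicate 2 (0.85, adjusted p = 0.212). Cd7 was higher at a ratio of 506 (counting interval 142 to 4246), and Pax5 did not pass (0.67 ± 0.26, adjusted p = 0.15). Ebf1 was lower (-0.94 ± 0.19, adjusted p = 0.0069), and did not pass without wild type replicate 2 (0.0787) or Pax5-KO with Pax5 replicate 1 (0.0844). Without wild type replicate 2, Pax5-KO with Pax5 replicate 1 or replicate 2 the number of genes was 433, 688 and 441.

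Genes that fell on loss of a factor were compared with those that rose when it was added back, in tests that share the empty-vector knockout libraries. Of the genes lower in Ebf1-KO, 210.0 rose with Ebf1, against 21.3 for independent lists, and of those higher 85 fell, against 8.90. The correlation across genes was -0.42, against -0.50 in simulation, and the covariance -1.49 against -0.46, a difference of -1.03. Of the genes lower in Pax5-KO 180.0 rose with Pax5, against 11.9, and of those higher 276 fell, against 30.2. Here the correlation was -0.62 against -0.50, and the covariance -2.10 against -0.46, a difference of -1.65. The knockout groups have 2 libraries each and were not split, so part of each excess may come from the shared controls. With no shared libraries, Ebf1 raised 128 genes in both knockouts, against 5.63 for independent lists, and lowered 44, against 2.05 (correlation across genes 0.339). Pax5 raised 113 in both, against 7.49, and lowered 32, against 3.26 (0.167). In opposite directions, 29 genes rose with Pax5 in Ebf1-KO and fell with it in Pax5-KO, more than independent lists give (Fisher's exact test adjusted p = 2.9e-06), and 1 did the reverse, against 2.22.

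EBF1 binding was described by 17230 peaks, each 320 bp wide, with scores from 12 to 578 (median 41) as the authors gave them. Of these 15507 had a start within 100 kb, and 7009 of 14550 tested genes (48.2%) had at least 1 peak. Genes that rose when Ebf1 was added to Ebf1-KO cells had a peak in 81.6% of cases (odds ratio 4.94, Fisher's exact test adjusted p = 1.4e-35), and those that fell in 59.5% (1.63, adjusted p = 0.0140). In Pax5-KO cells the shares with Ebf1 were 76.1% (3.52, adjusted p = 5.7e-20) and 59.1% (1.60, adjusted p = 0.00022). Of genes lower in Ebf1-KO 76.2% had a peak (3.80, adjusted p = 3.1e-76) and of those higher 51.0% (1.23, adjusted p = 0.00070). In Pax5-KO it was 72.2% of the lower (3.04, adjusted p = 9.1e-43) and 54.8% of the higher (1.42, adjusted p = 6.4e-09). Genes that rose with Pax5 had a peak in 77.7% of cases in Ebf1-KO (3.91, adjusted p = 4.6e-39) and 78.2% in Pax5-KO (4.00, adjusted p = 9.7e-22), and those that fell in 54.4% (1.34, adjusted p = 0.101) and 66.8% (2.25, adjusted p = 7.4e-13). Genes not called had a peak in 45.7 to 47.5% of cases. With a limit of 10 kb the odds ratio of genes higher in Ebf1-KO was 0.957 (adjusted p = 0.501), that of genes lowered by Ebf1 1.35 in Ebf1-KO and 1.21 in Pax5-KO (adjusted p = 0.164 for both). With mean expression in a logistic model that of genes lowered by Ebf1 in Ebf1-KO was 1.25 (adjusted p = 0.283).

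Between 100 kb upstream and 2 Mb downstream of the Myc start lay 27 EBF1 peaks on chromosome 15 (mm10). The highest score, 240, belonged to the peak at 63636716 to 63637036, 1651.5 kb downstream, followed by 215 at 62698708 to 62699028 and 186 at 63657815 to 63658135. Next came 140 at 63312650 to 63312970 and 130 at 63619969 to 63620289, and all 5 lay outside the genes of the count table. The peak closest to the start lay 1.498 kb upstream with a score of 103.

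Contacts of the Myc promoter fragment in H3K4me3 PLAC-seq numbered 9143 in the pooled wild-type profile and 17349 in the pooled Ebf1-KO profile, 89.1% and 90.8% of them on chromosome 15. Without contacts inside 20 kb, 8754 and 16470.0 remained. The share from 0.02 to 0.5 Mb downstream was 19.4% in wild type and 27.3% in Ebf1-KO (ratio 1.41, interval 1.33 to 1.49). From 0.5 to 1 Mb it was 15.9% and 18.5% (1.17, 1.09 to 1.24). It was lower in Ebf1-KO upstream, at 15.4% against 20.5% (0.751, 0.707 to 0.799), from 1 to 1.5 Mb, at 8.40% against 9.85% (0.853, 0.783 to 0.930), and from 1.5 to 2 Mb, at 14.4% against 15.5% (0.924, 0.864 to 0.988). Beyond 2 Mb the shares were 7.47% and 6.34%, and on other chromosomes 11.4% and 9.72%. In windows of 50 kb, the one at 63585341 to 63635340 took 3.62% in wild type and 2.94% in Ebf1-KO (0.812, 0.703 to 0.938), and its neighbour at 63635341 to 63685340, which holds 5 EBF1 peaks, 3.61% and 3.36% (0.930, 0.809 to 1.07, an interval that spans 1). The next, 63685341 to 63735340, took 3.39% and 3.47% (1.02, 0.887 to 1.18), and the window at 63285341 to 63335340, with 2 peaks, 1.09% and 0.553% (0.509, 0.378 to 0.686). The window at 62785341 to 62835340, with 2 peaks, took 2.99% and 4.44% (1.49, 1.29 to 1.72), and that at 62185341 to 62235340 1.78% and 3.11% (1.75, 1.46 to 2.10). The windows were named because of their values, and that at 63285341 to 63335340 had the lowest ratio of those downstream. Ratios upstream went lower, as at 61535341 to 61585340, which took 0.571% and 0.164% (0.287, 0.173 to 0.467). EBF1 peaks farther than 100 kb upstream were not counted. The intervals of windows are not adjusted for the number of windows. Shares sum to the whole, so a higher share in one region lowers the others, and the profiles have no replicates.

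Of 198 bins of 10 kb, 24 held an EBF1 peak. With a peak, wild-type contacts were 1.20 times as high after distance was allowed for (permutation p = 0.043 by circular shifts). Ebf1-KO contacts were 1.14 times as high (permutation p = 0.117). The wild-type value did not pass with 25 kb bins (1.07, permutation p = 0.36), nor with only the higher-scoring peaks, where it was 1.22 over 16 bins with a peak (permutation p = 0.063). The difference between genotypes was not tested.

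**Figure D3:**
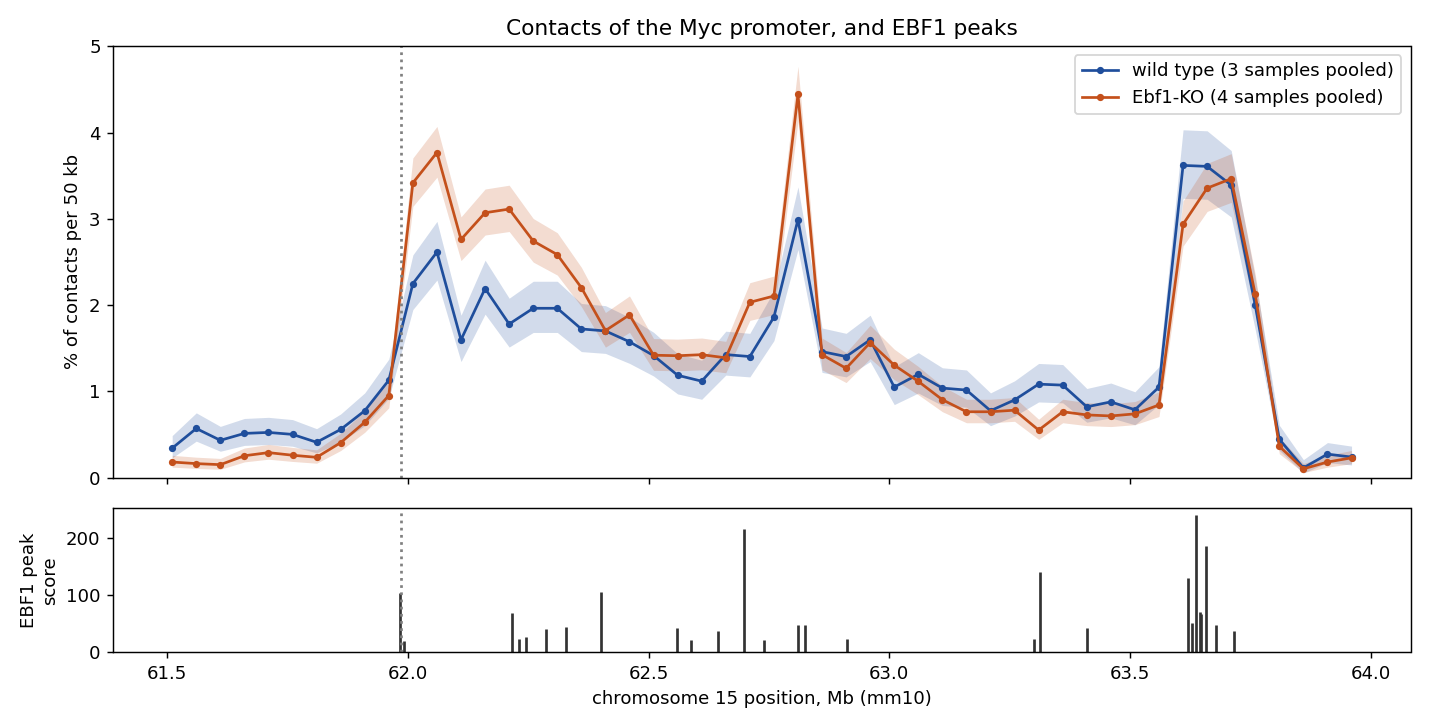
Percent of Myc promoter contacts per 50 kb window (top, y axis) with exact 95% binomial bands, for the wild-type profile of 3 pooled samples and the Ebf1-KO profile of 4, above the scores of EBF1 peaks (bottom, y axis), along chromosome 15 in Mb of mm10 (x axis, dotted line at the Myc start). Just downstream of the start the Ebf1-KO share lay above wild type, as at 62185341 to 62235340 (3.11% against 1.78%), and at 63585341 to 63635340 below it (2.94% against 3.62%).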

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

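The results in this part were picked out because a vector's effect differed between Ebf1-KO and Pax5-KO cells in a test of the difference itself. The interaction tests of genes were planned, while the list tests of the differences and the tests of explanations were chosen after the results were seen. Values are log2 differences, the effect in Pax5-KO cells minus the effect in Ebf1-KO cells, from edgeR for genes and as medians with camera for lists.

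Adding Pax5 lowered Myc in Ebf1-KO cells (-1.13, adjusted p = 0.021, not passing without 3 of the 4 libraries in turn, with 0.182, 0.161 and 0.0502), and in Pax5-KO cells Myc was higher with Pax5 without passing (0.91, adjusted p = 0.060; with the replicate block 0.91, adjusted p = 0.00893), a difference of 2.04 (adjusted p = 0.0062). A difference carried by 1 run, that is 1 replicate number, is argued against by the smaller of the within-run values, 1.95. One from scaling or tool is argued against by the smaller of the values with RLE and DESeq2, 1.99. One carried by 1 library is argued against by the lowest leave-one-out value, 1.77. A candidate explanation that stays open is that the higher Ebf1 after adding Pax5 to Pax5-KO cells carries the higher Myc there, where Ebf1 gave 0.28 against empty vector (adjusted p = 0.57). Myc in Pax5-KO cells was lower with Ebf1 than with Pax5 in both runs, by -0.64 (adjusted p = 0.145), which passed with the replicate block (-0.64, adjusted p = 0.0434) and without Pax5-KO with Ebf1 replicate 2 (-0.94, adjusted p = 0.0381), but not without any 1 of the other 3 libraries (adjusted p = 0.166 to 0.629), so these values count against that explanation without excluding it. Whether the genotype sets the direction was not tested apart from other differences between the cultures, such as sex, which coincide with it.

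The Pax5 effect differed for 460.0 genes and the Ebf1 effect for 89. Igll1 and Vpreb2, surrogate light chain genes, had lower Ebf1 effects in Pax5-KO cells, by -10.18 and -13.24, as did Clgn (-9.27) and Col26a1 (-11.23). The Pax5 effect was lower there for Lrrc15 (-8.15) and higher for Pcdh9 (8.61). Pax5 itself is the gene deleted in Pax5-KO cells, and its differences were -4.68 for the Ebf1 effect and -2.25 for the Pax5 effect. With empty vector Pax5 stood at 2.36 CPM in Ebf1-KO and 16.2 in Pax5-KO cells, and with the Pax5 vector at 414 and 593. The lower Pax5 effect on these reads thus lay in their higher level in Pax5-KO cells before Pax5 was added. The calls of genes named in this paragraph passed with each library of the comparison left out in turn. Fitted values of genes at 0 counts in a group depend on the prior count and are no bounds.

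The following genes passed and lost the call in some of the 8 fits that each left out 1 library. For the Ebf1 effect, Adgre1 (5.52) passed only without Ebf1-KO replicate 1 or either Pax5-KO with Ebf1 replicate (largest adjusted p = 0.123, without Pax5-KO replicate 2). Atp10a (1.65) passed only without Pax5-KO with Ebf1 replicate 2 (largest 0.291, without Pax5-KO replicate 2). Lrp1 (2.88) passed only without Pax5-KO replicate 1 or Pax5-KO with Ebf1 replicate 2 (largest 0.164, without Ebf1-KO with Ebf1 replicate 2). Hmga2 (3.16), which overlaps 9230105E05Rik and Mir763, lost the call without Ebf1-KO with Ebf1 replicate 2 (0.0544), Pax5-KO replicate 1 (0.061) or Pax5-KO replicate 2 (0.0571). The fifth gene with a higher Ebf1 effect in Pax5-KO cells was Ugcg (1.34), named after its value was seen.

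For the Pax5 effect, Alpl (16.21) lost the call without Ebf1-KO replicate 1 (adjusted p = 1). Col5a2 (-8.64) passed only without Ebf1-KO with Pax5 replicate 2 or Pax5-KO replicate 1 (largest 0.0983, without Ebf1-KO replicate 1), and Itgax (-8.00) only without Ebf1-KO with Pax5 replicate 1 or Pax5-KO replicate 1 (largest 0.222, without Pax5-KO replicate 2). Enpep (9.62) lost the call without Ebf1-KO replicate 1 (0.139) or 2 (0.0941) or Pax5-KO replicate 2 (0.0552). Slamf6 (-11.08) lost it without Ebf1-KO replicate 1 (0.0673) or 2 (0.0556), Pax5-KO replicate 2 (adjusted p = 1) or Pax5-KO with Pax5 replicate 2 (0.0685). Zfp521 (7.64) lost it without Ebf1-KO replicate 1 (0.367), Ebf1-KO with Pax5 replicate 1 (0.0531) or 2 (0.0753), or Pax5-KO replicate 2 (0.0589).

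For lists, the Ebf1 effect in Pax5-KO cells was lower on early B genes (-4.15, adjusted p = 2.8e-20). With Ebf1 this list had a mean log2 CPM of 5.14 and 5.21 in Ebf1-KO libraries and 5.14 and 5.24 in Pax5-KO libraries. With empty vector it had 1.22 and 1.28 against 4.66 and 4.78, so the difference lay in the levels before Ebf1 was added. It was also lower on ribosome biogenesis (-0.47, adjusted p = 0.0141, or adjusted p = 0.612 with an estimated correlation), nucleotide synthesis (-0.52, 0.0028, or adjusted p = 0.538 with an estimated correlation) and T lineage genes (-0.95, 0.0020, or adjusted p = 0.0892 with an estimated correlation), and higher on interferon genes (1.29, 2.2e-06, or adjusted p = 0.0651 with an estimated correlation).

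The Pax5 effect in Pax5-KO cells was lower on T lineage (-1.94, adjusted p = 4.0e-07), NK and innate lymphoid (-2.86, 2.2e-06) and myeloid genes (-1.98, 3.8e-05), which also passed with an estimated correlation (adjusted p = 0.0164 for each). It was higher on ribosome biogenesis (1.22, adjusted p = 9.6e-10, or adjusted p = 0.178 with an estimated correlation), nucleotide synthesis (0.93, 2.2e-05, or adjusted p = 0.354), glycolysis (0.94, 0.0016, or adjusted p = 0.502), DNA replication (0.69, 5.1e-05, or adjusted p = 0.354) and mitosis (0.39, 0.0141, or adjusted p = 0.597). It was lower on brakes (-0.77, adjusted p = 0.00037, or adjusted p = 0.0558 with an estimated correlation), the BCL2 family (-0.48, 0.0141, or adjusted p = 0.147), IL-7 and PI3K signalling (-0.79, 0.00061, or adjusted p = 0.354), stem and progenitor genes (-1.76, 0.0019, or adjusted p = 0.147) and interferon genes (-0.95, 0.0016, or adjusted p = 0.178).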

How the results depend on the processing

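The alternatives were planned before the data were examined, apart from the list tests with 1 library left out. Over them, 387 named results gave 3062 values with the same direction and side of the threshold, 66 that newly passed, 316 that no longer passed and 1 of opposite sign. That was Ebf1 with Pax5 added to Ebf1-KO cells, where the log2 fold change ran from -0.175 to 0.081, the latter without Ebf1-KO replicate 2. Of 340 named calls 252 held with any 1 library left out. Where 1 library of a group is left, it is assumed to vary like the other groups. The EBF1 motif alternatives were not run. RLE scaling moved no Myc call and no count of genes past these limits. For the changes below the cause was not tested, except that fits of only the compared groups or without 1 library have fewer samples.

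With DESeq2 in place of edgeR, 1101 genes were lower in Pax5-KO, 265 fell with Ebf1 in Ebf1-KO, and 831 rose and 368 fell with Pax5 in Ebf1-KO. In Pax5-KO 695 rose and 811 fell with Ebf1, and 406 rose and 703 fell with Pax5. The Ebf1 effect differed for 224 genes and the Pax5 effect for 1147, the vectors for 2308 in Ebf1-KO and 2023 in Pax5-KO, and Pax5-KO with Pax5 from wild type for 1741. Without the filter on low counts the numbers were 256 lower with Ebf1 in Ebf1-KO, and 701 higher and 301 lower with Pax5 in Ebf1-KO. They were 560.0 and 670.0 with Ebf1 in Pax5-KO, and 380.0 and 663 with Pax5 in Pax5-KO. They were 269 and 940.0 for the differing effects, 1732 between vectors in Pax5-KO and 1604 against wild type. In fits of only the compared groups they were 527 higher and 428 lower with Ebf1 in Ebf1-KO, 53 and 14 with Ebf1 in Pax5-KO, and 408 and 658 with Pax5 in Pax5-KO. They were 859 for the differing Pax5 effect, 202 between vectors in Pax5-KO, and 2472 and 1802 for Ebf1-KO with Ebf1 and Pax5-KO with Pax5 against wild type.

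With the replicate number as a block, 264 genes fell with Pax5 in Ebf1-KO, 439 with Ebf1 in Pax5-KO, and the Pax5 effect differed for 737. Myc then passed in Ebf1-KO against wild type (-0.76, adjusted p = 0.00996), with Pax5 in Pax5-KO (0.91, 0.00893) and between vectors in Pax5-KO (-0.64, 0.0434). The value against wild type assumes a shared run that the pairs with wild type did not show. The block changed no other Myc call or count past these limits and no list call in the 6 main comparisons. With it 17 further results of named genes newly passed, and the list tests of differing effects were not run with it. Myc also passed in Ebf1-KO with DESeq2 (-0.73, adjusted p = 0.0255), without the filter (-0.73, 0.0198) and with only those groups (-0.73, 0.0309), and with Pax5 in Pax5-KO likewise (0.88, 0.0116; 0.87, 0.00773; 0.91, 0.0337).

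With an estimated correlation 7 lists passed in Ebf1-KO, 3 with Ebf1 and 2 with Pax5 in Ebf1-KO, and 2 with Ebf1 and 4 with Pax5 in Pax5-KO; with fry 5 passed with Ebf1 in Ebf1-KO and 7 with Pax5 in Pax5-KO. With peaks within 10 kb the odds ratio of genes higher in Ebf1-KO turned to 0.957, and those of genes lowered by Ebf1, 1.35 in Ebf1-KO and 1.21 in Pax5-KO, no longer passed, nor did 1.25 in Ebf1-KO with mean expression in a logistic model. As shares of contacts within 2 Mb only, the ratio was 0.662 upstream and 1.33 from 0.02 to 0.5 Mb. The test of contacts at EBF1 peaks in wild type no longer passed with 25 kb bins (1.07) or the higher-scoring peaks (1.22).

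Leaving out each library in turn, higher and lower counts ran from 683 to 891 and 511 to 713 in Ebf1-KO, 672 to 1047 and 290.0 to 567 in Pax5-KO, 153 to 231 and 24 to 51 with Ebf1 and 131 to 291 and 28 to 66 with Pax5 in Ebf1-KO. They ran from 53 to 830.0 and 72 to 1398 with Ebf1 and 95 to 144 and 117 to 251 with Pax5 in Pax5-KO. Differing effects ran from 48 to 685 for Ebf1 and 133 to 342 for Pax5, vector differences from 635 to 939 in Ebf1-KO and 333 to 2644 in Pax5-KO, and add-back against wild type from 879 to 1218 and 433 to 749. The log2 fold change of Myc ran from -0.96 to -0.53 in Ebf1-KO, 0.02 to 0.34 in Pax5-KO, 0.90 to 1.36 with Ebf1 and -1.34 to -0.90 with Pax5 in Ebf1-KO. It ran from -0.024 (without Pax5-KO with Ebf1 replicate 2) to 0.52 with Ebf1 and 0.66 to 1.11 with Pax5 in Pax5-KO. It ran from -1.16 to -0.62 and 1.77 to 2.24 for the differing Ebf1 and Pax5 effects, 2.03 to 2.47 and -0.94 to -0.39 between vectors, and 0.17 to 0.62 and 0.85 to 1.30 for add-back against wild type. Lists ran from 9 to 12 in Ebf1-KO, 10 to 12 in Pax5-KO, 7 to 11 with Ebf1 and 7 to 10 with Pax5 in Ebf1-KO, and 1 to 6 with Ebf1 and 8 to 12 with Pax5 in Pax5-KO. At 2 libraries a group the simulated test called 9 of 100 changes of 1 log2 unit with Ebf1 in Ebf1-KO, so changes of that size were mostly missed in that simulation. It changed fewer genes than the 432 called in this comparison in the data, so it does not give the share missed there.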

Other observations

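Mycn, Hoxa9 and Pvt1 and the tests of explanations were chosen after the results were seen. Mycn, a paralogue of Myc, had 25.1 ± 5.96 CPM in wild type and 207 ± 44.2 in Ebf1-KO (log2 fold change 3.04 ± 0.42, adjusted p = 0.00012). Adding Ebf1 to Ebf1-KO cells lowered Mycn to 41.2 ± 10.0 CPM (-2.33, adjusted p = 0.00389) and adding Pax5 to 63.8 ± 1.09 (-1.70, adjusted p = 0.0266). In Pax5-KO cells Mycn had 35.9 ± 10.3 CPM (0.52 against wild type, adjusted p = 0.444), 9.70 ± 6.49 with Ebf1 (-1.87, adjusted p = 0.0198) and 15.9 ± 3.43 with Pax5 (-1.18, adjusted p = 0.137).

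Hoxa9, a homeobox gene of blood progenitors, was higher in Ebf1-KO (8.98 ± 0.58, adjusted p = 6.5e-08) and in Pax5-KO (5.89 ± 0.53, adjusted p = 2.5e-06) than in wild type. It fell in Ebf1-KO cells with Ebf1 (-1.71 ± 0.39, adjusted p = 0.0252) and with Pax5 (-1.66 ± 0.39, adjusted p = 0.0266). The integrin gene Itgb7 fell with Ebf1 in Ebf1-KO cells (-3.17 ± 0.46, adjusted p = 0.00093), and Chrna4, a nicotinic receptor subunit, fell with Pax5 in Pax5-KO cells (-5.14 ± 0.58, adjusted p = 0.00019). The receptor gene Notch3 fell with Pax5 in Ebf1-KO cells (-2.27 ± 0.38, adjusted p = 0.0029). Pvt1, the non-coding RNA gene next to Myc, had 32.0 ± 12.1 CPM in wild type and 13.7 ± 7.96 in Ebf1-KO (-1.23, adjusted p = 0.127, not passing). It had a similar level in Pax5-KO, at 13.6 ± 2.12 CPM, and in Ebf1-KO with Ebf1, at 11.7 ± 0.673.

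Myeloid, NK and T lineage genes were higher in both knockouts than in wild type. Too few counts in wild type is argued against for the myeloid list, since its 1624 wild-type counts are 6.64% of the smaller number expected at a knockout level. Admixed myeloid cells stay open: over 12 members the Pax5-KO to Ebf1-KO ratio had an SD of 1.33 log2 units, 2.85 times the 0.467 that replicates give, but replicate spread may be technical and sets no bound for separate cultures. Adding Pax5 lowered the myeloid list in Pax5-KO cells (median -1.47), which goes with the hypothesis that loss of Pax5 raises it there. In Ebf1-KO cells adding Pax5 lowered neither it (0.38) nor T lineage (0.03) or NK genes (0.79). Adding Ebf1 there gave the myeloid list -0.25 (adjusted p = 0.332), which decides nothing for loss of Ebf1. Loss of admixed cells on adding Pax5, other mixtures and other culture differences stay open and were not tested.

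Xist and Y-linked genes differed between wild type and Pax5-KO cultures, so sex coincides with this genotype. Genes on X or Y made up 2.42% of the calls between them. X held only 3.18% of the genes tested, and 4 of the calls lay on Y. Such genes were too few to make up most of the calls, so this share decides nothing about sex. Sex as the whole cause of the autosomal calls would not link them to adding Pax5 in Ebf1-KO cells, but among the 281 of 1938 autosomal calls that were also called there the odds ratio of opposite directions was 17.7 (Fisher's exact test p = 4.46e-15). That association rests on genes lower in Pax5-KO, of which 158 rose and 6 fell with Pax5, while of those higher 70.0 rose and 47 fell. Sex as part of the cause of autosomal calls stays open.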
